A study of Mus musculus with 12 samples.

How the data were processed

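Liver RNA from male C57BL6/J mice was measured on a whole-transcript Affymetrix-type mouse gene array, with 12 samples and 1 array per sample. Per the labels' protocols, the animals were 8 to 10 weeks old, were kept at 22 °C under 12 h of light and 12 h of dark, and received an Ad5 adenovirus through the tail vein. They were killed 4 days later, at 3 pm after 6 h without food, and RNA was purified on columns from 20 mg of frozen liver. The virus named in the labels put 6 samples in the GFP group (replicates 1 to 6) and 6 in the group given human ApoF (hApoF, replicates 7 to 12). The replicate numbers are not shared between the groups, and the labels give no batch and no viral dose. The labels speak of mice but do not state sample by sample that each array came from its own animal, so the p-values measure the spread between these samples.

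The deposited table holds log2 values per probe set. The submitters' processing notes name oligo and RMA, the robust multi-array average, which consists of background correction, quantile normalization and a median-polish summary. Versions, parameters, the genome build and the annotation release are not given in the sources used here. The values were used as deposited, with 35145 probe sets, 12 arrays and 0 missing values. Array medians lay between 4.93 and 5.03 and upper quartiles between 6.67 and 6.81 on the log2 scale, and pairwise correlations between arrays (across probe sets, which are not independent replicates) between 0.982 and 0.993. The spread of values differed between the groups. Lower quartiles were 3.659 to 3.718 in GFP arrays other than GFP 4 and 3.741 to 3.796 in hApoF arrays. Upper quartiles were 6.734 to 6.814 and 6.668 to 6.726. GFP 4 (3.798 and 6.673) resembled the hApoF arrays in this. The number of arrays limits the precision.

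Probe sets were named through the platform annotation supplied with the values, which can be old. Of the 35145 probe sets, 23521 had 1 gene symbol, 1814 had several genes and 9810 had none listed. Probe sets with several genes or none were named after no gene and stayed out of the main comparison. Gene numbers of 23328 single-gene probe sets matched a mouse gene table for the assembly GRCm38.p6, which was used for names only, and 0 symbols needed updating. Each of the 22180 genes was represented by its probe set with the highest mean over all 12 arrays. A total of 1082 genes had more than 1 probe set. No filter on dim probe sets was applied.

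The comparison of hApoF with GFP was fitted in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with default settings, no covariates), with p-values adjusted by the Benjamini-Hochberg method over all genes and a threshold of 0.05. Adjusted p-values given for single genes are from this fit. Fold changes are log2 differences, hApoF minus GFP, with the fit's standard error (SE). Gene lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, fry and an exact two-sided permutation test of the list mean per array over the 924 assignments of 6 of the 12 arrays were also run. The smallest p this permutation test can give is 0.0022. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

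The gene lists, the rule for named genes, the tests of genes and lists and all but 1 of the alternatives were chosen before the data were examined. The 32 lists held 698 entries, of which 631 were on the array under 1 symbol. The others were not analysed here. The lists cover lipoproteins and lipid metabolism, bile acids, glucose, protein folding, inflammation, cell cycle and p53 targets, detoxification, sex-biased and clock genes, hepatocyte zones, mitochondria, ribosomes and markers of other cell types and tissues. Some genes are in more than 1 list. All lists had at least 5 measured members. The genes named are Apof, the 12 changed genes with the largest rise and the 12 with the largest fall (leaving out predicted genes and multigene receptor, immunoglobulin and small RNA symbols), and from each list up to 4 members with the lowest p among those that passed, or at most 2 where none passed. Any other gene named was chosen after its values were seen. The 2 further lists, of immediate-early genes and of complement and coagulation genes, were also written after the values were seen.

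The fit and the list test were tested on simulated values for the same 22180 genes in 6 against 6 arrays. Of 50 genes changed by 0.5 on the log2 scale 56% were recovered, and 100% of the 50 genes at each of 1, 1.5 and 2, with 18 false calls. A simulated list shifted by 0.5 was called, and without any change 0 genes and 0 lists were called. The simulated genes were drawn independently of each other. In the measured lists members moved together, with estimated correlations up to 0.66 (cell cycle). The simulated values therefore do not show how often camera with the preset 0.01 calls lists falsely here.

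The alternatives were centring each array on its median, a further quantile normalization, leaving out the dimmest genes (the lowest tercile by mean level), eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, all named probe sets, an adjusted p below 0.01, a fold change of at least 1.5, the other list tests, and leaving out each array in turn. Leaving out GFP 4 and hApoF 12 together was added after the data were seen, because these arrays lay apart from their groups on the first 2 principal components. No coordinates are given, because the build behind the annotation is not known.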

Results

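Gene expression was measured in liver 4 days after intravenous injection of an adenovirus carrying either human apolipoprotein F or green fluorescent protein (GFP), the latter being the control virus. ApoF is a secreted protein carried on lipoproteins, also known as lipid transfer inhibitor protein. Each group had 6 arrays, and the deposited values were log2 RMA values for 22180 named genes. The question addressed is which liver transcripts differ when human ApoF is overexpressed. Both groups received a virus, and uninjected livers were not analysed here.

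Livers given hApoF had lower levels of proliferation and p53 target transcripts than livers given GFP virus, and higher levels of cholesterol synthesis transcripts. The exact permutation test of list means called these 3 lists after adjustment, and camera with an estimated correlation did not (adjusted p = 0.072, 0.072 and 0.214). The largest fall was that of the spindle protein gene Ckap2, 5.55-fold (log2 change -2.47, SE 0.23, limma with Benjamini-Hochberg, adjusted p = 1.4e-05). The largest rise among genes that passed was that of the immediate-early transcription factor gene Fos, 3.06-fold (log2 change 1.61, SE 0.45, limma adjusted p = 0.041). In all, 1533 genes (6.91%) changed, 469 higher and 1064 lower, so that 69.4% of the changed genes were lower. At least 1.5-fold changes were seen in 73 higher and 368 lower genes, and at least 2-fold changes in 13 and 148. The values of the groups did not overlap for 1104 genes, 4.98% of all genes, where chance gives 0.217%. The median log2 change of all genes was 0.03. The number of changed genes was 1019 without GFP 2, 1015 without GFP 3 and 1021 without GFP 6, and the number of higher genes 307 without GFP 1, 254 without GFP 2, 267 without GFP 3 and 267 without GFP 6.

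The mouse gene Apof did not differ between the groups. Its level was 11.06 ± 0.08 (SD, n = 6) in GFP livers and 11.10 ± 0.11 (n = 6) in hApoF livers, a log2 difference of 0.04 (SE 0.07, limma adjusted p = 0.792, exact permutation p = 0.470). The transferred gene is human and the probe set was designed for mouse, so this value does not check the group labels.

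After Ckap2, the largest falls among named genes were those of Ect2, a cytokinesis regulator (log2 change -2.40), Hmmr, a hyaluronan receptor active at the spindle (-2.37), Cdkn1a, the p53-induced cyclin-dependent kinase inhibitor p21 (-2.29), Prc1 (-2.24), Depdc1a (-2.19), the cyclin gene Ccnb2 (-2.19), Cdkn3 (-2.08), the mitotic kinesin gene Kif20a (-2.06), the kinetochore gene Knl1 (-2.05), the p53-induced receptor gene Eda2r (-2.03) and the glutathione transferase gene Gstp3 (-2.03). In each of these 12 genes no hApoF array reached the level of any GFP array, and Gstp3 had the lowest adjusted p of them (limma, 4.3e-07). The hApoF means of Depdc1a (4.39), Eda2r (4.40) and Hmmr (4.58) lay below the array medians. The largest rises of named genes that passed, after Fos, were those of Fabp5, a fatty acid binding protein (1.52, limma adjusted p = 0.0036, with 4 probe sets between 1.31 and 1.52), Nipal1 (1.42), the Kupffer cell receptors Vsig4 (1.38) and Clec4f (1.26), Igfbp1, an insulin-repressed binding protein (1.19), the p53-inducible antiproliferative gene Btg2 (1.12), the immediate-early gene Ier2 (1.10), Cib3 (1.07), the sterol synthesis enzyme Msmo1 (1.05), the phosphatase gene Acpp (1.04) and Sqle, squalene epoxidase (1.03). Fos lost its call in 9 of the 12 fits that left out 1 array (limma adjusted p up to 0.095, without GFP 6), Vsig4 in 7 (up to 0.088, without GFP 2), Igfbp1 in 5 and Ier2 in 4 (both up to 0.057, without GFP 2), and Cib3 had an adjusted p of 0.060 without GFP 4 and hApoF 12 together. With trend and robust settings these values were 0.10 for Fos, 0.090 for Vsig4, 0.061 for Igfbp1 and 0.053 for Ier2.

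**Figure D1:**
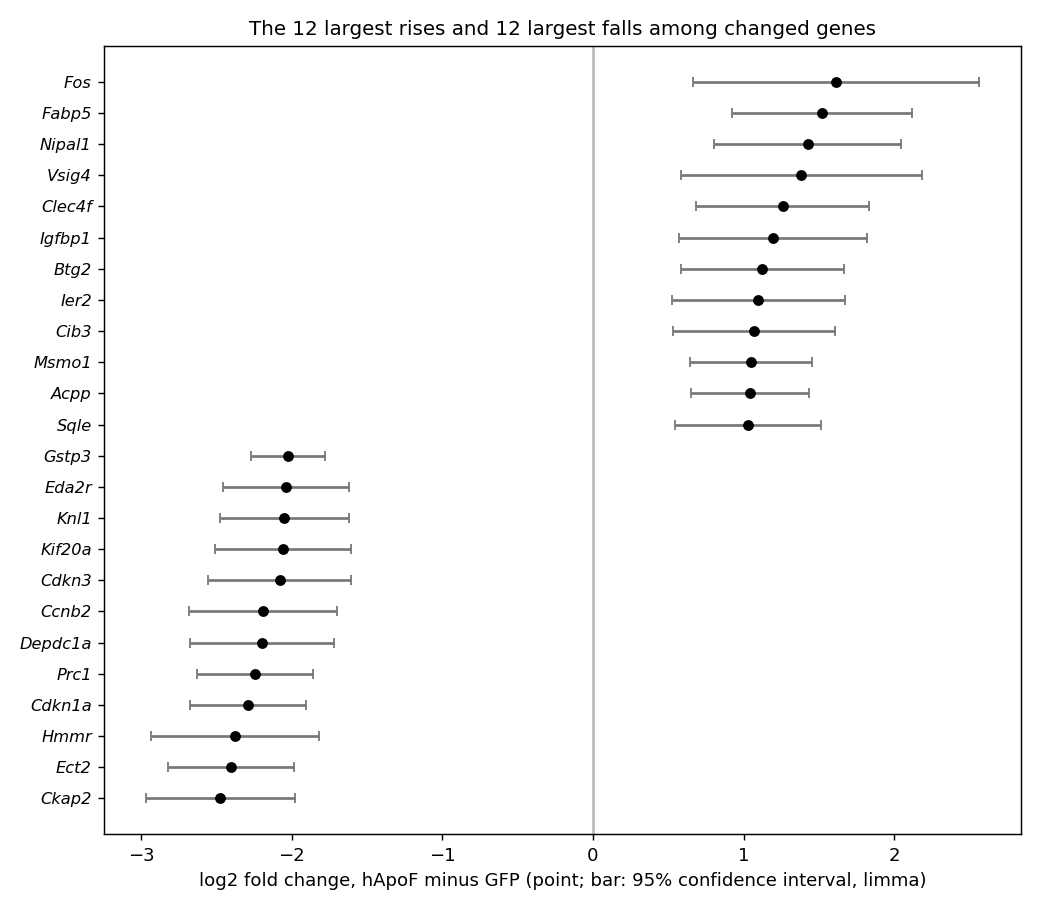
Log2 fold change (hApoF minus GFP, horizontal axis) of the 12 named genes with the largest rise and the 12 with the largest fall among genes with a limma adjusted p below 0.05, as points with 95% confidence intervals from 6 arrays per group. The falls run from -2.47 (Ckap2) to -2.03 (Gstp3) with narrower intervals than most of the rises, which run from 1.03 (Sqle) to 1.61 (Fos).

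Cell cycle genes were lower nearly throughout their list. Of 24 measured members 23 fell, 1 rose and 0 did not pass, and adjusted over the list alone the counts were also 23 and 1. Examples with limma values are Plk1, a mitotic kinase (log2 change -2.00, SE 0.17, adjusted p = 9.8e-06), Cdc20, an activator of the anaphase-promoting complex (-1.68, SE 0.14), Aurka, a spindle pole kinase (-1.66, SE 0.14), and Kif11, a spindle motor (-1.72, SE 0.16). The member that rose was Ccnd1, cyclin D1, which acts in the first gap phase (0.66, limma adjusted p = 0.026), a call lost without GFP 2, GFP 5, GFP 6 or hApoF 11. The mean level of the list was 7.50 ± 0.23 (SD, n = 6) in GFP livers and 6.15 ± 0.31 (n = 6) in hApoF livers. It fell by 1.35 (exact permutation p = 0.0022, 0.012 after adjustment over the lists), and the median change was -1.49 (camera, adjusted p = 2.8e-38; adjusted p = 0.072 with an estimated correlation). Without GFP 4, the GFP array with the lowest cell cycle level (7.13), and hApoF 12, the hApoF array with the lowest (5.61), 23 members were lower and 1 higher.

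Of 18 measured genes of the p53 response and apoptosis list, 11 fell, 2 rose and 5 did not pass, and adjusted over the list alone 11 fell and 2 rose. Besides Cdkn1a and Eda2r, limma gave falls of Gtse1, a regulator of p53 in dividing cells (log2 change -1.18, SE 0.12), and of Ccng1, cyclin G1, a p53 target (-0.79, SE 0.10). The risers were Btg2 and Sesn1, a stress-induced inhibitor of growth signalling (0.46). The median change was -0.53 (camera, adjusted p = 5.7e-10; adjusted p = 0.072 with an estimated correlation), and the mean level fell by 0.53 (exact permutation p = 0.0022). Without GFP 4 and hApoF 12 the counts were 11 lower and 2 higher. Beside these falls, the mean level of the endothelial marker list was higher in hApoF livers by 0.26 and that of the macrophage and Kupffer cell list by 0.31.

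**Figure D2:**
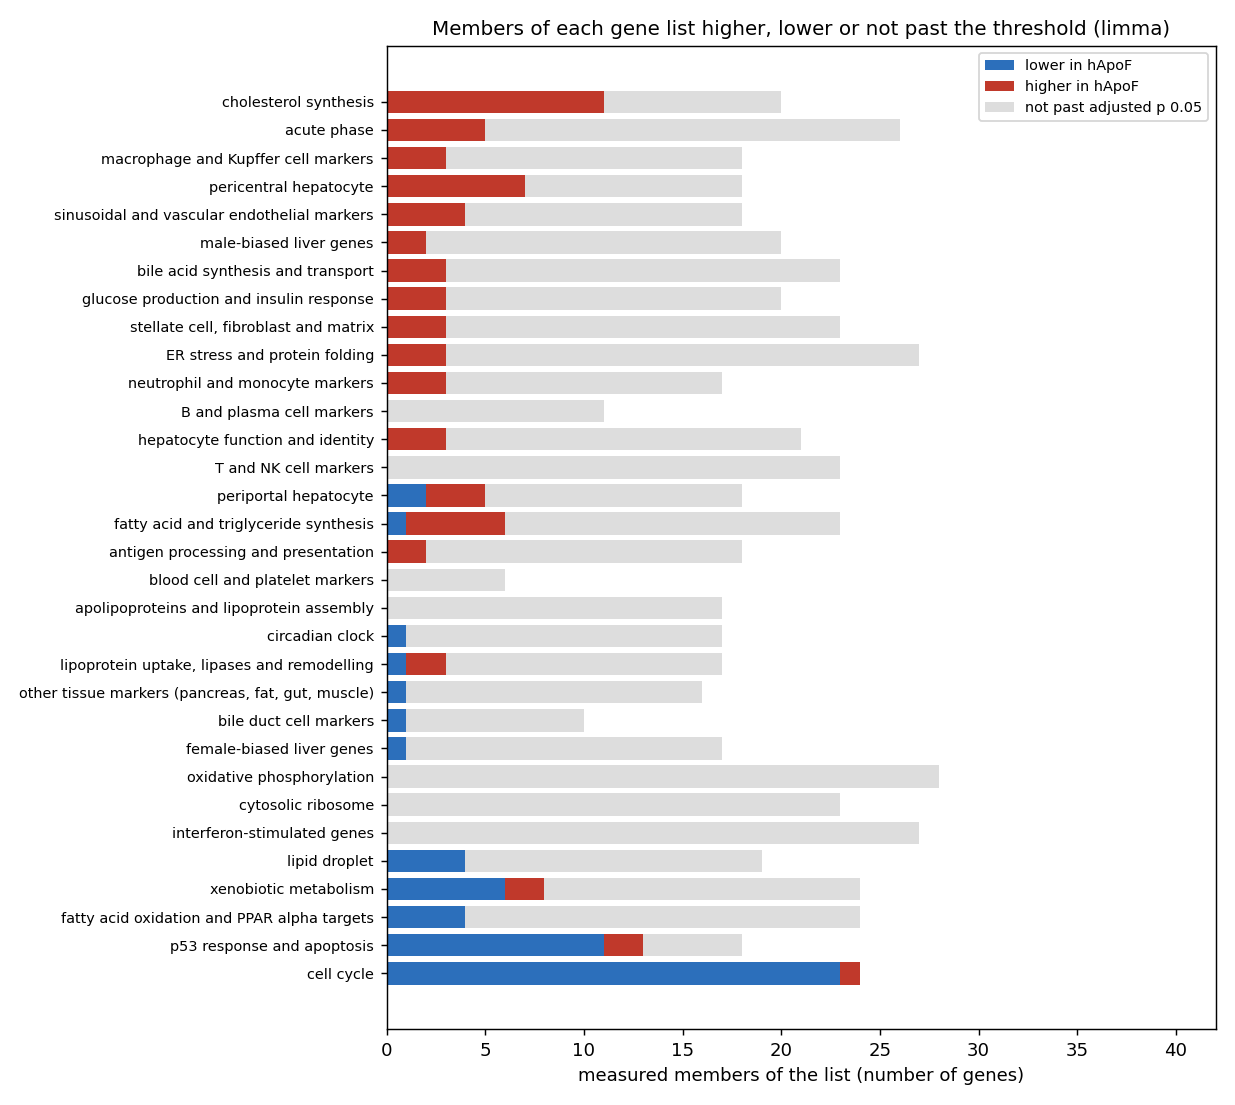
Number of measured genes (horizontal axis) in each of the 32 lists that were lower in hApoF (blue), higher in hApoF (red) or not past a limma adjusted p of 0.05 (grey), ordered by mean log2 fold change. Cell cycle (23 lower, 1 higher), p53 response (11 lower, 2 higher) and cholesterol synthesis (11 higher, 0 lower) hold the most changed genes.

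Genes of cholesterol synthesis were higher. Of 20 measured members 11 rose, 0 fell and 9 did not pass, and adjusted over the list alone 15 rose. Limma gave rises of Insig1, a sterol-regulated anchor of the SREBP pathway (log2 change 0.67, SE 0.09, adjusted p = 3.1e-04), Hsd17b7 (0.80, SE 0.14) and Tm7sf2 (0.51, SE 0.09), enzymes of the late pathway, and Msmo1 (1.05, SE 0.19). The mean level was 8.38 ± 0.14 (SD, n = 6) in GFP livers and 8.92 ± 0.27 (n = 6) in hApoF livers, higher by 0.54 (exact permutation p = 0.0022). Camera gave an adjusted p of 5.1e-12, and the adjusted p was 0.214 with an estimated correlation. Without GFP 4 and hApoF 12, 9 members were higher.

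Fatty acid oxidation and PPAR alpha target genes were lower in part. Of 24 measured, 4 fell, 0 rose and 20 did not pass, and adjusted over the list alone 9 fell. Acot2, a mitochondrial acyl-CoA thioesterase with a close paralog, fell by 1.88 (SE 0.27, limma adjusted p = 4.1e-04), and Pex11a, a peroxisome division gene, by 0.37, Slc25a20, the carnitine carrier, by 0.32 and Hadhb, a subunit of the trifunctional protein, by 0.41. The median change was -0.24 (camera, adjusted p = 1.1e-05; adjusted p = 0.342 with an estimated correlation) and the exact permutation p of the mean level 0.011 (adjusted 0.032). In the lipid droplet list 4 of 19 fell, 0 rose and 15 did not pass, against 8 lower and 1 higher adjusted over the list alone. The fallers were Cidec, a droplet fusion protein (-0.68, limma adjusted p = 0.0086), Fitm2 (-0.35), Hsd17b13 (-0.29) and Plin3 (-0.26), with a median change of -0.17 (camera, adjusted p = 2.6e-04; adjusted p = 0.214 with an estimated correlation). Only Acot2 and Cidec of these 8 genes kept their call in every omission of 1 array, and the number of lower genes went down to 1 in each list without GFP 2, GFP 3, GFP 6 or hApoF 7, and to 2 without hApoF 9 in each and without hApoF 8, hApoF 10 or hApoF 12 in the droplet list. Without GFP 4 and hApoF 12 the counts were 7 and 3.

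Fatty acid and triglyceride synthesis genes went both ways, with 5 of 23 higher, 1 lower and 17 not past the test, and 7 higher and 4 lower adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, rose by 0.75 (limma adjusted p = 0.0029), Acacb, an acetyl-CoA carboxylase, by 0.56 and Lpin2, a phosphatidate phosphatase, by 0.29, while Dgat1, a triglyceride-forming acyltransferase, fell by 0.47 (limma adjusted p = 8.5e-04). The list as a whole did not pass (camera, adjusted p = 0.764; adjusted p = 0.959 with an estimated correlation), Lpin2 lost its call without GFP 3 (limma adjusted p = 0.059) or hApoF 10, and the count of higher genes was 2 without GFP 3 and 3 without GFP 2, GFP 5, GFP 6 or any of hApoF 7, 8, 9, 10 and 12. None of the 17 apolipoprotein and lipoprotein assembly genes passed the limma test, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (3 higher, 1 lower). The lowest p were those of Mttp, the triglyceride transfer protein that loads apolipoprotein B (-0.22, limma adjusted p = 0.058, with no overlap between groups), and Apoa4 (0.51, limma adjusted p = 0.121). Mttp passed when arrays were centred (limma adjusted p = 0.049), quantile normalized again (0.033), fitted with trend and robust settings (0.016) or restricted to brighter genes (0.030), and without hApoF 9 (0.042). Apoa4 passed without hApoF 10 (limma adjusted p = 0.019), and without hApoF 12 a count of 1 gene of the list was higher. In the list of lipoprotein uptake, lipases and remodelling 2 of 17 rose, 1 fell and 14 did not pass, against 3 and 3 adjusted over the list alone. Mylip, a ligase that degrades the LDL receptor, rose by 0.50 (limma adjusted p = 8.7e-04) and Pltp, phospholipid transfer protein, by 0.48, and Angptl4, a lipoprotein lipase inhibitor, fell by 0.34. The camera adjusted p was 0.950 for the apolipoprotein list and 0.992 for the uptake list, where camera pointed down and the median and mean up. The means of both lists, 0.03 and 0.01, turned negative when arrays were centred on their medians. Pltp lost its call in 7 of 12 omissions (limma adjusted p up to 0.080, without GFP 6). The higher count of the uptake list was 1 without GFP 3, GFP 6, hApoF 7, hApoF 9 or hApoF 10, and its lower count 2 without GFP 5.

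In the bile acid list 3 of 23 rose, 0 fell and 20 did not pass, with 7 higher adjusted over the list alone. Slc27a5, a bile acyl-CoA synthetase, rose by 0.64 (SE 0.10, limma adjusted p = 0.0013), and the uptake transporters Slco1a1 and Slco1a4, members of a multigene family, by 0.55 and 0.64. Camera gave an adjusted p of 0.0015, and 0.214 was the adjusted p with an estimated correlation. The exact permutation p was 0.0043 (adjusted 0.020). Of the 24 xenobiotic metabolism genes 6 fell, 2 rose and 16 did not pass, against 12 and 5 adjusted over the list alone. Gstm3 fell by 1.25, Gstm1 by 0.66 (both glutathione transferases of a family with near-identical members) and Ephx1, microsomal epoxide hydrolase, by 0.70 (limma adjusted p = 0.0022), while Nr1i3, the nuclear receptor CAR, rose by 0.72 (limma adjusted p = 5.3e-05). Camera gave an adjusted p of 0.018, and 0.342 was the adjusted p with an estimated correlation. Slco1a4 lost its call in 5 of 12 omissions (limma adjusted p up to 0.059, without GFP 6) and without GFP 4 and hApoF 12 together (0.068), when the xenobiotic counts were 8 lower and 3 higher.

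Genes of pericentral hepatocytes, the cells around the central vein, were higher in part. Of 18 measured 7 rose, 0 fell and 11 did not pass, and 11 rose adjusted over the list alone. Gulo, an enzyme of vitamin C synthesis, rose by 0.58 (limma adjusted p = 0.0053), the glutamate transporter gene Slc1a2 by 0.40, Lect2 by 0.43 and Glul, glutamine synthetase, by 0.26. The median change was 0.29 (camera, adjusted p = 2.3e-06; adjusted p = 0.216 with an estimated correlation; exact permutation p = 0.0022). The count was 2 without GFP 2 or GFP 6, 4 without hApoF 9 or hApoF 10, and 10 without GFP 4 and hApoF 12, and Glul lost its call in 4 omissions and Lect2 in 2. Of 18 periportal genes 3 rose, 2 fell and 13 did not pass (4 and 3 adjusted over the list alone), with rises of Pigr, the immunoglobulin transporter, by 0.52, of Pck1, the gluconeogenic enzyme, by 0.44 and of Hal, histidine ammonia-lyase, by 0.66. The fallers were Hsd17b13 (-0.29, limma adjusted p = 0.039) and Hsd17b6 (-0.64, limma adjusted p = 0.047). The list did not pass (camera, adjusted p = 0.206; adjusted p = 0.562 with an estimated correlation). Camera called the periportal list without hApoF 12 (adjusted p = 0.045) and without GFP 4 and hApoF 12 together (0.048). The lower count of that list was 0 without GFP 1, GFP 2, GFP 3, GFP 6, hApoF 8, hApoF 9 or hApoF 10, and 1 without GFP 4, hApoF 7 or hApoF 12. Hal lost its call without GFP 2, GFP 3 (limma adjusted p = 0.055) or GFP 6. Whether the pericentral and periportal lists differ was not tested.

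Of 21 hepatocyte identity genes 3 rose, 0 fell and 18 did not pass, with 4 higher adjusted over the list alone. They were Kng1, kininogen (log2 change 0.36), the clotting factor gene F7 (0.28) and Hpd, an enzyme of tyrosine breakdown (0.32), and the list had a median of 0.07 (camera, adjusted p = 0.016; adjusted p = 0.249 with an estimated correlation). In the glucose and insulin list 3 of 20 rose, 0 fell and 17 did not pass (8 higher and 1 lower adjusted over the list alone), namely Pck1 (limma adjusted p = 0.0020), Igfbp1 and Insr, the insulin receptor (0.28). Camera gave an adjusted p of 0.058 for it, and 0.562 was the adjusted p with an estimated correlation. The list was called in 6 of 12 omissions (camera, adjusted p down to 0.025, without hApoF 8) and without GFP 4 and hApoF 12 together (0.035). Male-biased genes had 2 of 20 higher and 0 lower (3 higher adjusted over the list alone), Slco1a1 and Susd4 (0.56, limma adjusted p = 0.0069), and female-biased genes 1 of 17 lower and 0 higher (1 lower and 2 higher adjusted over the list alone), Cyp17a1 (-0.61, limma adjusted p = 0.042). Their camera adjusted p were 0.054 and 0.936, and the female-biased list had a median above and a mean below 0. The male-biased list was called in 5 of 12 omissions (camera, adjusted p down to 0.0086, without GFP 4, when 4 genes were higher) and without GFP 4 and hApoF 12 together (0.0087). With an estimated correlation over all arrays its adjusted p was 0.562. In the female-biased list 1 gene was higher without hApoF 8 or hApoF 11. Of 17 clock genes Clock alone changed (-0.39, limma adjusted p = 0.027), also adjusted over the list alone, and the list's camera adjusted p was 0.919. The glucose count was 1 without GFP 1, GFP 2, GFP 6 or hApoF 9 and 6 without GFP 4, and the hepatocyte identity count 1 without GFP 2, GFP 3, GFP 6, hApoF 7, hApoF 9 or hApoF 10. F7 lost its call in 6 of the 12 omissions of 1 array, Hpd in 9, Insr in 7, Cyp17a1 in 8 and Clock in 6, with limma adjusted p up to 0.109 (Hpd, without GFP 6).

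Among 27 genes of protein folding in the endoplasmic reticulum 3 rose, 0 fell and 24 did not pass, the same counts as adjusted over the list alone. The chaperone genes Dnajb9 and Dnajc3 rose by 0.53 and 0.30 (limma adjusted p = 0.0045 and 0.0090) and Edem1, a degradation factor, by 0.38 (camera, adjusted p = 0.0038; adjusted p = 0.342 with an estimated correlation; exact permutation p = 0.0022). Of 26 acute phase genes 5 rose, 0 fell and 21 did not pass, with 11 higher adjusted over the list alone. Crp, C-reactive protein, rose by 0.38 (limma adjusted p = 0.0051), Orm1 by 0.62, Cebpd by 0.47 and Mt1, a metallothionein, by 0.50, the median being 0.28 (camera, adjusted p = 4.3e-06; adjusted p = 0.342 with an estimated correlation). The exact permutation p of the acute phase mean was 0.115. Without single arrays the acute phase count lay between 1 (without GFP 1, GFP 3 or GFP 6) and 8 (without GFP 5; 7 without hApoF 12), the folding count was 5 without hApoF 12, Mt1 lost its call in 10 of 12 omissions, Cebpd and Edem1 in 7 and Orm1 in 5.

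None of the 27 interferon-stimulated genes passed the limma test, over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05 (1 higher, 6 lower). Oasl1 and Usp18, both induced by type I interferon, had log2 changes of -0.41 and -0.54 (limma adjusted p = 0.064 and 0.067). The list's median was -0.15 (camera, adjusted p = 0.0093; adjusted p = 0.562 with an estimated correlation; exact permutation p = 0.136), its camera call was lost without GFP 3 or hApoF 7 (camera, adjusted p = 0.058), and 3 genes were lower without hApoF 9 and 2 without GFP 4. Oasl1 passed with centring (limma adjusted p = 0.048), array weights (0.048), trend and robust settings (0.043) and brighter genes only (0.039), and Usp18 with brighter genes only (0.042). Both passed without hApoF 9 (limma adjusted p = 0.021 and 0.044), and Usp18 also without GFP 4 (0.0496). Of 18 antigen presentation genes 2 rose, 0 fell and 16 did not pass (3 higher and 1 lower adjusted over the list alone), the class II genes H2-Ab1 (0.51, limma adjusted p = 0.0058) and H2-Aa (0.57, limma adjusted p = 0.025). Camera gave an adjusted p of 0.538 for that list, 2 of its genes were lower without GFP 4, and H2-Aa lost its call without GFP 2 (limma adjusted p = 0.063), GFP 6, hApoF 11 or hApoF 12.

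Markers of endothelial cells and macrophages were higher in part in hApoF livers. Of 18 endothelial markers 4 rose, 0 fell and 14 did not pass, and 11 rose adjusted over the list alone. Kdr, a receptor for vascular endothelial growth factor, rose by 0.44 (limma adjusted p = 0.0089), the angiopoietin receptor gene Tek by 0.41, the sinusoidal Fc receptor gene Fcgr2b by 0.37 and Dnase1l3 by 0.34. The mean level was 7.67 ± 0.17 (SD, n = 6) in GFP and 7.94 ± 0.10 (n = 6) in hApoF livers (exact permutation p = 0.015, 0.040 after adjustment over the lists; camera, adjusted p = 1.4e-06; adjusted p = 0.342 with an estimated correlation). Of 18 macrophage and Kupffer cell markers 3 rose, 0 fell and 15 did not pass, also adjusted over the list alone. They were Clec4f (limma adjusted p = 0.010), Vsig4 and the scavenger receptor gene Cd163 (0.96), with a list median of 0.13 (camera, adjusted p = 0.023; adjusted p = 0.531 with an estimated correlation; exact permutation p = 0.0498, 0.098 after adjustment over the lists). GFP 4 had the highest level of both lists among GFP arrays (7.92 and 7.33), and without it 9 endothelial markers rose and 3 macrophage markers, Cd163 not among them. The endothelial count was 5 without hApoF 7 and 3 without any other single array. The macrophage count was 1 without GFP 1, GFP 2, GFP 3, hApoF 7 or hApoF 11, its camera call was lost without GFP 2 (camera, adjusted p = 0.168) or hApoF 9, and Dnase1l3 lost its call in 10 and Cd163 in 6 of 12 omissions. Without GFP 4 and hApoF 12 the counts were 6 endothelial and 4 macrophage genes.

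Of 23 stellate cell and matrix genes 3 rose, 0 fell and 20 did not pass (8 higher adjusted over the list alone), namely Hgf, hepatocyte growth factor (0.40, limma adjusted p = 0.013), Dcn, decorin (0.26), and Pdgfrb (0.28), with camera adjusted p = 4.7e-04 and adjusted p = 0.342 with an estimated correlation. Of 17 neutrophil and monocyte markers 3 rose, 0 fell and 14 did not pass, also adjusted over the list alone: Ccr2 (0.46, limma adjusted p = 0.0063), Mmp8 (0.52) and S100a9 (0.40), with camera adjusted p = 0.020 and adjusted p = 0.342 with an estimated correlation. None of 23 T and NK cell, 11 B and plasma cell and 6 blood cell and platelet markers passed the limma test over all genes. Unadjusted p under 0.05 numbered 3 higher and 1 lower in the T and NK list, 2 higher in the B and plasma list and 1 higher in the blood list, and adjusted over the list alone 1 blood marker was higher. The lowest p were those of Cd4 (-0.25, limma adjusted p = 0.085), Cd79a (0.27, limma adjusted p = 0.063) and Itga2b (0.26, limma adjusted p = 0.076). Camera gave adjusted p of 0.241, 0.059 and 0.699 for these lists. Without GFP 4, 2 B and plasma cell markers, Cd79a among them (limma adjusted p = 0.023), and the blood marker Itga2b (0.021) passed as higher. Without GFP 4 and hApoF 12 together, 2 B and plasma cell markers and 1 blood marker were higher. Camera called the B and plasma cell list without GFP 4 (adjusted p = 0.026), hApoF 8 or hApoF 11. Over all arrays its adjusted p was 0.342 with an estimated correlation. Of 10 bile duct markers Krt23, a keratin, fell by 1.12 (limma adjusted p = 1.4e-04), 0 rose and 9 did not pass (1 higher and 2 lower adjusted over the list alone), and the list's median was above and its mean below 0 (camera, adjusted p = 0.992). In that list 2 genes were lower without hApoF 7 or hApoF 11, and 1 was higher without GFP 5 or hApoF 10. Of 16 markers of pancreas, fat, gut and muscle Car3 alone fell (-0.27, limma adjusted p = 0.046), also adjusted over the list alone, while the median and mean were above 0 and camera pointed down (adjusted p = 0.992). Dcn, Pdgfrb and S100a9 lost their calls in 9 of 12 omissions each and Car3 in 11. The stellate count was 1 without GFP 1, GFP 2, GFP 3, GFP 6, hApoF 7, hApoF 8 or hApoF 12, and the neutrophil and monocyte list lost its camera call without hApoF 11 (camera, adjusted p = 0.062).

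None of 28 oxidative phosphorylation and 23 ribosomal protein genes passed the limma test, over all genes or adjusted over the list alone. Unadjusted p under 0.05 numbered 4 and 3, all of them lower in hApoF livers. The lowest p were those of Ndufv1 (-0.23, limma adjusted p = 0.057), Sdhd (-0.24, limma adjusted p = 0.072), Rpl13 (-0.18, limma adjusted p = 0.080) and Rps9 (-0.18, limma adjusted p = 0.158). List medians were -0.05 and -0.06, with camera adjusted p of 0.030 and 0.013, and adjusted p of 0.562 and 0.249 with an estimated correlation. The exact permutation p of the mean levels were 0.134 and 0.011 (adjusted 0.218 and 0.032). The oxidative phosphorylation call was lost without hApoF 7 or hApoF 12 (camera, adjusted p = 0.142). Ndufv1, Sdhd and Rpl13 passed with trend and robust settings (limma adjusted p = 0.024, 0.030 and 0.031). Both lists are bright, with mean levels of 9.13 and 8.20 in GFP livers. Upper quartiles of the arrays were also lower in hApoF (6.668 to 6.726) than in GFP arrays other than GFP 4 (6.734 to 6.814). Whether other genes as bright shifted alike was not tested. Nor was this tested for the dim B and plasma cell and neutrophil and monocyte lists, where lower quartiles differed the other way.

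**Figure D3:**
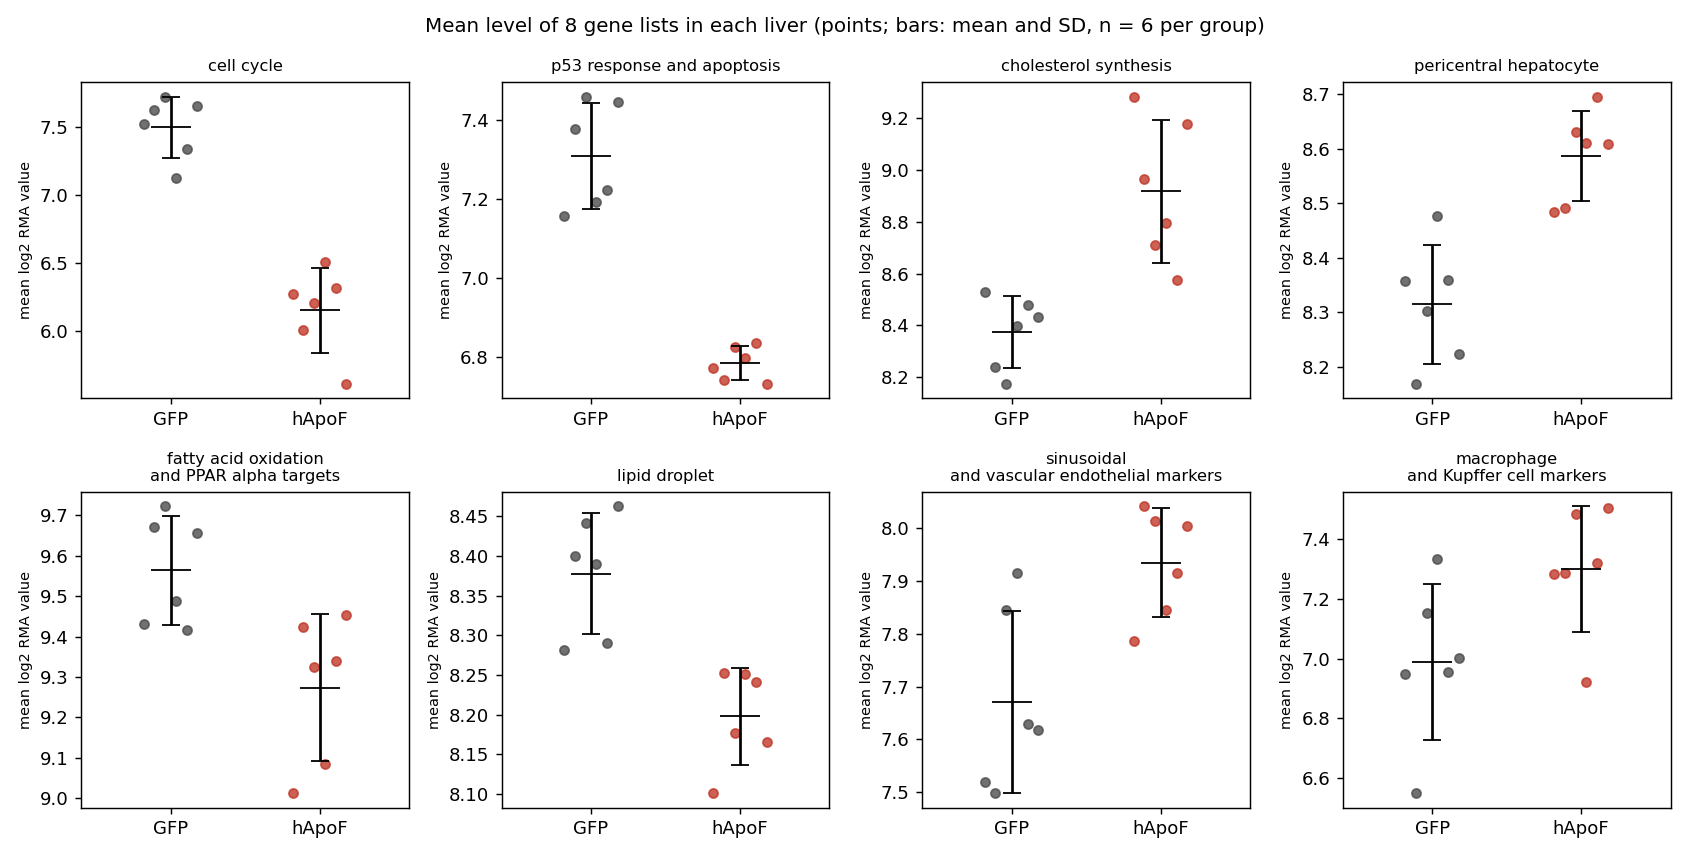
Mean log2 RMA value over the measured members of 8 lists (vertical axes, a separate scale for each panel, not starting at 0) in each of the 6 GFP and 6 hApoF arrays, as points with the group mean and SD as bars. The groups separate fully for cell cycle, p53, cholesterol synthesis, pericentral and lipid droplet lists and overlap for the fatty acid oxidation, endothelial and macrophage lists.

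Over the 32 lists camera called 18, of which 10 were higher and 8 lower. With an estimated correlation camera called 0 of them, and 6 had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in a single direction, called 11, and the exact permutation test of list means called 12 after adjustment. Among those 12 were the cell cycle, p53, cholesterol synthesis, fatty acid oxidation, lipid droplet and bile acid lists. The others were the protein folding, endothelial, xenobiotic, pericentral, hepatocyte identity and ribosomal protein lists. Camera also called at least 18 lists in 5 of 100 splits of the 12 arrays into groups of 6, the real split included.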

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

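Leaving out 2 arrays together was chosen only after the values were seen; the search for samples far from their group was planned. In each group of 6 arrays, the highest or lowest value was compared with its nearest neighbour by Dixon's test for the named genes and the gene list means. Of 276 groups tested 12 had such a sample (4.35%), about as many as the 1 in 20 that chance gives, so no weight is put on the number.

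Among the genes that fell, Cdkn1a was at 10.01 in GFP 3 against 9.15 to 9.41 in the other GFP arrays, and Gstp3 was at 11.36 in the same array against 10.81 to 11.01. The mitotic genes Kif20a and Cdc20 were lowest in hApoF 12, at 5.07 against 6.06 to 6.64 and at 5.75 against 6.33 to 6.65 in the other hApoF arrays. Eda2r was at 5.06 in hApoF 10 against 4.11 to 4.40. Among the genes that rose, Mylip was at 7.65 in hApoF 12 against 7.20 to 7.36, Slc27a5 at 10.33 in hApoF 12 against 10.66 to 10.82, Dnajc3 at 10.60 in GFP 5 against 10.47 to 10.50, and Pdgfrb at 6.65 in hApoF 10 against 6.83 to 6.88. The platelet gene Itga2b, which did not pass, was at 5.63 in hApoF 12 against 5.33 to 5.44. The mean level of B and plasma cell markers was 4.80 in GFP 4 against 4.58 to 4.65, and that of ribosomal protein genes 8.04 in hApoF 12 against 8.12 to 8.17.

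Of these 12 values 6 belong to hApoF 12, the array that also lay apart on the second principal component (30.8, other arrays -14.0 to 4.87; 11.9% of the variance). On the first component (31.7%) GFP 4, at 0.36, lay between the other GFP arrays (-26.9 to -10.8) and the hApoF arrays (11.2 to 20.6). Without both arrays 2049 genes changed, 1351 of them among the 1533 called with all arrays. The cause of these positions was not tested.

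Probe sets with several genes or none listed stayed out of the main comparison. Of these 11624, limma called 155 after Benjamini-Hochberg adjustment over them, 32 higher and 123 lower in hApoF livers. Their genes are not named here.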

How the results depend on the processing

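Leaving out GFP 4 and hApoF 12 together was chosen only after the data were seen; the other alternatives were planned. Each of the settings below that refitted the genes kept the direction of all genes it shared with the 1533: 1381 of 1490 called after centring each array, 1296 of 1521 after a further quantile normalization, 1432 of 2065 among brighter genes, 1498 of 1946 with trend and robust settings, 1502 of 1978 with array weights, 1485 of 1498 with the mean of a gene's probe sets and 1351 of 2049 without the 2 arrays. Genes called in both fits to nearly the same arrays can hardly differ in direction, so the kept direction adds no separate support. The share of changed genes that were lower was 69.4%, 78.7% after centring and 61.7% after quantile normalization. At an adjusted p below 0.01, 659 genes changed (123 higher, 536 lower), and at least 1.5-fold, 441 (73 higher, 368 lower). These stricter thresholds lower the counts by construction. Camera called 0 lists with an estimated correlation and fry called 11. In these lists members move together within groups, and the estimated correlations, up to 0.66 for cell cycle, replace the preset 0.01. Leaving out 1 array at a time gave 1015 (without GFP 3) to 1988 (without GFP 4) changed genes, 254 (without GFP 2) to 653 (without GFP 4) higher genes, 17 to 21 lists by camera and 7 (without GFP 2 or GFP 6) to 16 (without GFP 4 or hApoF 10) lists by exact permutation, where the full set gave 1533, 469, 18 and 12. Fewer arrays alone lower the power, and for the differences between omissions the cause was not tested. Apof stayed between 0.01 and 0.07 and was called in no omission.

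Lists near 0 changed sign. After centring, the mean change was -0.0013 for apolipoproteins, -0.019 for lipoprotein uptake, -0.0041 for the clock and -0.025 for other tissues, and -0.025 for other tissues after quantile normalization. Single omissions gave -0.0088 to 0.041 for lipoprotein uptake (below 0 without GFP 2, GFP 6 or hApoF 9) and -0.021 to 0.030 for other tissues (below 0 without GFP 3, GFP 6, hApoF 7, hApoF 8 or hApoF 9). None of these lists was called in any of these settings. The blood list and S100a9 had no value among brighter genes.

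Of the 105 named genes other than Apof, 91 were called with all arrays and 14 were not. Over the 12 single omissions 876 calls of the 91 were kept, 216 ended and 7 calls of the 14 were added. Over the other settings 610 were kept, 26 ended and 23 were added, and not every added call is named here. None of the 105 changed sign. Camera no longer called the neutrophil and monocyte list (adjusted p = 0.052), hepatocyte identity (0.052) and oxidative phosphorylation (0.063) after quantile normalization, nor, among brighter genes, the neutrophil and monocyte (0.061), oxidative phosphorylation (0.130), interferon (0.053) and xenobiotic (0.065) lists. Oxidative phosphorylation was also not called with array weights (0.059) or without the 2 arrays (0.164). The male-biased and glucose lists were called after centring (0.024 and 0.030), among brighter genes (0.031 and 0.040), with trend and robust settings (both 0.037), array weights (0.028 and 0.029) and the mean of probe sets (both 0.049), and the B and plasma cell list after centring (0.045). Beyond those given with the results, calls ended by limma adjusted p were those of Lpin2 (0.057), Mt1 (0.055), S100a9 (0.054), Dnase1l3 (0.070), Dcn (0.060), Pdgfrb (0.062) and Hpd (0.061) after centring, Hadhb (0.057), Plin3 (0.079), S100a9 (0.071) and Hpd (0.098) after quantile normalization, Lpin2 (0.087), Edem1 (0.099), Glul (0.080) and Car3 (0.086) with the mean of their probe sets, Cd163 (0.051) with trend and robust settings, and Fitm2 (0.070), Mt1 (0.088), H2-Aa (0.068) and Car3 (0.085) without the 2 arrays. Below the array medians lay the means of Krt23 (4.10), Depdc1a (4.39), Eda2r (4.40), Hmmr (4.58) and Cd4 (4.91) in hApoF livers, and those of Mmp8 (4.25 and 4.77), S100a9 (3.97 and 4.37), Cd79a (4.41 and 4.68) and Klrd1 (4.38 and 4.80) in GFP and hApoF livers. Signal over background was not measured. No paired analysis was possible because the groups share no replicate number.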

Other observations

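The tests of immune cell loss, virus or injury, hepatocyte share (with its pairs of marker lists and genes restricted to Kupffer cells) and time of day were chosen only after the result was seen, as were the lists of immediate-early and of complement and coagulation genes. The tests of array scaling (plain and brightness-dependent), a single array and other splits of the arrays were written before their results.

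Immediate-early genes, which are transcribed within minutes of a stimulus, were higher in part in hApoF livers. Of 26 measured 6 rose, 1 fell and 19 did not pass the limma test over all genes, and 10 rose and 1 fell adjusted over the list alone. Besides Fos, Ier2 and Btg2, limma gave rises of Zfp36, an mRNA decay factor (log2 change 0.85, adjusted p = 0.038), Junb (0.72, adjusted p = 0.036) and the kinase gene Sik1 (0.68, adjusted p = 0.019), while the repressor gene Klf10 fell by 0.57 (adjusted p = 0.035). Egr1 had 1.15 and Jun 0.99, which did not pass (limma adjusted p = 0.075 and 0.061). The mean level was higher by 0.43 (exact permutation p = 0.043; camera, adjusted p = 5.3e-04; adjusted p = 0.231 with an estimated correlation). The list was written after its leading genes had been seen, so its test is not independent evidence.

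Of 25 complement and coagulation genes 2 rose, 1 fell and 22 did not pass, with 9 higher and 1 lower adjusted over the list alone. Masp1, a protease of the lectin pathway, rose by 0.99 (SE 0.12, limma adjusted p = 1.2e-04) and C8a, a part of the membrane attack complex, by 0.73 (limma adjusted p = 4.5e-04). Mbl2, a mannose-binding lectin that acts with Masp1, fell by 0.60 (limma adjusted p = 0.0020). The groups did not overlap for these 3 genes. Camera gave an adjusted p of 6.8e-04, and 0.231 was the adjusted p with an estimated correlation. Within the macrophage list, 6 genes largely restricted to Kupffer cells had a mean 0.80 higher in hApoF livers (exact permutation p = 0.011), and 9 genes of macrophages in general 0.03 (exact permutation p = 0.844). These sub-sets were picked with the values known.

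Chance assignment of arrays can be excluded for the number of changed genes. Of 100 splits of the 12 arrays into groups of 6, drawn from 462 and including the real split, 1 gave as many, the real value being 1533 and the highest of the others 1. It cannot be excluded for the number of lists that camera called: 5 of the 100 splits gave at least 18, the highest of the others gave 20, and the median of the others was 7. Such splits cannot address a batch or an order of handling that coincided with the virus. The labels give no batch, so for each pattern below this cannot be told apart from the virus.

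The first pattern is the lower level of cell cycle and p53 target genes. Array scaling is argued against for a fall of this size, since the array medians lay only between 4.93 and 5.03. The median change of the cell cycle list was -1.52 with centring and -1.47 with quantile normalization. With array values so alike, these steps could move it little, so they add no separate support. Fewer dividing macrophages cannot be told apart: macrophage and Kupffer markers were higher by 0.31 and a fall of 0.5 was excluded (exact permutation p = 0.0022), but genes restricted to Kupffer cells rose by 0.80 and general macrophage genes by 0.03, and resident macrophages would hide the loss of a small dividing share. Fewer T and NK cells cannot be told apart from these data. Their markers (difference 0.08) had a mean level of 4.92, below the array medians, and whether a loss would show at that level was not tested. More virus or injury in the GFP livers cannot be told apart either. Interferon-stimulated genes differed by -0.16 (exact permutation p = 0.136) and acute phase genes, the other way, by 0.33 (exact permutation p = 0.115). Viral dose is not given in the sources used here. A lower proliferative response with human ApoF may be the biological alternative, as a hypothesis that cannot be separated from an effect of the GFP virus without uninjected livers.

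The second pattern is the higher level of endothelial and Kupffer markers. Brightness-dependent scaling is argued against for the endothelial list. In the deposited values this list was higher by 0.26, while other genes of the same brightness had a median change of -0.03. The list was higher by 0.30 after a further quantile normalization, but RMA values are already quantile normalized, so that step adds no separate support. Kupffer markers were not tested in this way. A lower share of hepatocytes may raise the markers of all other cell types alike. The endothelial, stellate and macrophage lists differed in their rise by at most 0.14 (lowest adjusted exact permutation p = 0.244). Of 8 marker lists the bile duct (-0.04), blood (0.04) and T and NK cell (0.08) lists moved least, at mean levels near or below the array medians. The B and plasma cell (0.14) and neutrophil and monocyte (0.15) lists also lay below the array medians and rose more. Over the 28 pairs of these 8 lists the lowest exact permutation p was 0.0043, and 0.091 after adjustment. A single differing pair among 28 could not pass, since the smallest p this test can give is 0.0022. The genes restricted to Kupffer cells rose by 0.54 more than the endothelial list (exact permutation p = 0.041), against an equal rise, but they were picked with their values known. A lower share would lower hepatocyte transcripts. The hepatocyte identity list was instead higher by 0.09 (exact permutation p = 0.0065, 0.026 after adjustment over the lists) and the pericentral list by 0.27 (exact permutation p = 0.0022). The periportal list (0.07, exact permutation p = 0.245) did not pass. How far a lower share would lower such transcripts was not measured, and these genes can also change within the cells. The first 2 lists therefore cannot decide. The fatty acid oxidation and lipid droplet lists fell (-0.29 and -0.18) and cannot decide for the same reason. A lower hepatocyte share is neither shown nor excluded. A change in the cells themselves with human ApoF stays open and untested.

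The third pattern is the higher level of immediate-early genes. A single array as its source is argued against, since the difference of 0.43 was still 0.35 at the lowest of the 12 omissions. A planned difference in time of day at sacrifice is argued against, since the labels give 3 pm for all arrays of both groups. Smaller differences around that hour cannot be told apart. Limma called 0 of 8 clock genes with a strong daily rhythm adjusted over the clock list alone, and 1 had an unadjusted p under 0.05. The mean of the clock list differed by 0.03 (exact permutation p = 0.439). But the 95% intervals of the 8 genes reached from -0.51 to 0.79, and Clock, which is not among the 8, was lower by 0.39 (limma adjusted p = 0.027). Handling and the order of dissection could act on such genes within minutes and are not given in the sources used here. An effect of human ApoF stays open and untested.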
